A study of Caenorhabditis elegans with 2 samples.

How the data were processed

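The samples were 2 biological replicates of ChIP-seq from whole L2 larvae of the eGFP::NHR-11 strain, each with 1 technical replicate and fragments of 150 to 350 bp, per the labels. They form 1 group, so no contrast between groups was made. Peak lists on builds ce11 and ce10 were used for each replicate, for the pooled replicates, and for the thresholded set. Per the description deposited with the lists, the authors called peaks on each replicate's alignments, and on those of both together, against a control alignment. They kept unthresholded peaks and background as input to the irreproducible discovery rate (IDR) procedure, and took the thresholded list from the pooled and replicate lists. The aligner, the peak caller and all versions are not given in the sources used here, and the control library was not analysed here.

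The signal value of each peak is the caller's own, as the authors deposited it, and its scaling to depth or control is not given in the sources used here. It was used only to rank and describe peaks within a list and to correlate the replicates. The minus log10 q-value in the deposited lists was the same for all thresholded ce11 peaks and was not used to rank them. The summit offset in bp from the peak start, also deposited by the authors, gave each summit position. All 8 lists had the checksum recorded with them, and the 280 thresholded ce11 peaks were the 280 pooled peaks with the highest signal. One region was listed with more than 1 summit, leaving 279 distinct regions. Peak coordinates were compared with the reference chromosomes, and no ce11 peak ended beyond its chromosome.

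Coordinates are 1-based on ce11, the build of the Ensembl 115 annotation and RefSeq genome used here. The ce10 lists served only as an alternative, with no conversion between builds. Mitochondrial genes without a name in the annotation were named from RefSeq genes at the same position. A summit was assigned to every protein-coding gene for which it lay from 1000 bp upstream to 500 bp downstream of an annotated transcript 5′ end. Such a gene is called bound, which states the position of a peak only. Summits within 500 bp of a tRNA, snRNA, snoRNA, rRNA or miRNA gene were counted apart, because short RNA genes often give peaks with many factors.

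Chance placement came from 1000 circular rotations along each chromosome, with a smallest two-sided p of 0.002 and one-sided p of 0.001. Correlations used 100000 permutations and 10 were computed in all. The 35 gene lists and 20 motifs were fixed before the data were examined. Lists were tested with two-sided Fisher's exact tests against all 19973 nuclear protein-coding genes, and chromosome shares with exact binomial tests, both with Benjamini-Hochberg adjustment. Motif windows held 50 bp on each side of a summit, against a pair of windows of equal width centred 300 bp to either side. The exact sign test fixed for them compares the summit with the mean of its flanks and favours the flanks. An exact window exchange test, in which each of a peak's 3 windows is equally likely to be the summit's, was added after that was seen. Percentages carry 95% Wilson intervals, which cover counting error only. Because read counts were not part of the lists, depth per sample is unknown and no interval includes it. The replicate lists carry no shared scale, so no difference in signal between replicates was tested.

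Genes were named by a rule fixed beforehand: those assigned to the 15 strongest thresholded peaks, or the nearest gene where none was assigned; the 4 bound members of highest signal in each list past an adjusted p of 0.05 and up to 2 in other lists; nhr-11 and unc-119; and short non-coding genes near the 15 strongest summits. The 15 strongest nuclear peaks and some short non-coding genes were added after the values were seen, as were all values without mitochondrial peaks. Alternatives tried were build, merging of overlapping peaks, overlap rule, chance model, promoter and assignment windows, background, peak number, motif windows and controls, and leaving out each replicate. Leaving out a replicate meant using the 280 strongest unthresholded peaks of the other replicate's own list. It was not a repeat of the IDR thresholding.

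The tests were tested on simulated data. Of 100 sets of 250 randomly placed peaks, 4 were called for promoter share, and all 100 sets with 100 peaks planted at 5′ ends were called. With 60 shared peaks planted in 20 pairs of sets, 60 to 61 shared peaks were found and all 20 were called. Of 100 random sets of 160 genes, 1 had any list called, and all 100 with 8 ribosomal protein genes planted were called. Of 50 unrelated pairs of signal values 3 were called for correlation, and all 50 related pairs were. For motifs, the sign test called at least 1 motif in 23 of 40 random sets and the exchange test in 0, and both called a motif planted in 30 summit windows in all 40. For hexamers in 5 random sets, the sign test called 71 to 126 and the exchange test 0 to 1. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0.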

Results

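NHR-11 is a nuclear hormone receptor of the nematode Caenorhabditis elegans, a member of a family of ligand-regulated transcription factors that is unusually large in this species. Its sites on DNA were measured by ChIP-seq, in which chromatin fragments held by a protein are pulled down with an antibody, sequenced and called as peaks where they pile up above a control. The animals were whole L2 larvae of both sexes from strain OP305, which carries an integrated transgene with nhr-11 fused to eGFP in an unc-119 mutant background. There was 1 group with 2 biological replicates, and the question the design poses is where in the larval genome the tagged receptor was found. No second stage, mutant or untagged group was among the samples, so every comparison is between the replicates, or between the peaks and the genome. The thresholded list on genome build ce11 held 280 peaks, drawn from 13299 unthresholded peaks of the pooled replicates. The separate lists held 25831 unthresholded peaks for replicate 1 and 27015 for replicate 2. Signal values of the thresholded peaks ran from 27.4 to 447.5 with a median of 34.6, and the width of a peak had a median of 430 bp. Read counts were not part of the peak lists, so the sequencing depth of either replicate is unknown.

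The strongest peaks of the list lay on the mitochondrial genome, and the strongest nuclear peak lay in front of cdc-48.1, which encodes an AAA ATPase that extracts ubiquitinated proteins. Of the 15 peaks with the highest signal, 14 were mitochondrial. The highest was within the coding sequence of ND5, a subunit of respiratory complex I, with a signal of 447.5 (MtDNA 12190 to 12686; 313 in replicate 1 and 144 in replicate 2). Others in this set had their summits in COX2, COX3, ND2, CYTB, COX1 and ND1, or within the rRNA genes MTCE.7 and MTCE.33. Mitochondrial tRNA genes lay within 500 bp of most of these summits, such as MTCE.22 and MTCE.24 by a COX3 summit, MTCE.13, MTCE.14 and MTCE.15 by ND2, and MTCE.8, MTCE.9 and MTCE.10 by ND1. No chance share for mitochondrial peaks alone is given here, so this closeness is not read as an excess. The cdc-48.1 peak ranked 7 of 280 with a signal of 203 (chromosome II, 10563441 to 10563673; 121 in replicate 1 and 79.5 in replicate 2), its summit in intergenic sequence 178 bp upstream of the annotated 5′ end. Altogether 26 of the 280 peaks were mitochondrial, with a median signal of 130 against 32.99 for the 254 nuclear peaks.

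Because mitochondrial peaks filled nearly all of that set, the 15 strongest nuclear peaks are also described, a choice made after the values were seen. After cdc-48.1 came rpl-3, a protein of the large ribosomal subunit, with a signal of 118 at a summit 284 bp upstream (chromosome III, 3867479 to 3867659; 80.4 in replicate 1 and 36.1 in replicate 2). The 61 bp centred on that summit read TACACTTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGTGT. A peak of signal 99.5 on X (16930726 to 16931073) was intergenic and had no 5′ end within the assignment window, the nearest being that of C30E1.4. The next was shared by tasp-1 and K01G5.10 (signal 92.5, chromosome III, 10759176 to 10759317), with its summit 92 bp upstream of tasp-1. The 61 bp at its summit were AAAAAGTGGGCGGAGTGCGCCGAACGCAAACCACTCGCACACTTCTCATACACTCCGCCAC. The 14-3-3 gene ftt-2 had a peak of signal 88.1 at 513 bp upstream (X, 11605804 to 11605986), and dpf-3, a dipeptidyl peptidase gene, one of 76.1 at 242 bp upstream, its summit in the 3′ UTR of the neighbouring gene ahcy-1. A peak of signal 73.01 on chromosome II (5844751 to 5845180) had its summit within sls-2.1, a gene for the SL2 spliced leader RNA. The remaining nuclear peaks of this set lay by W02G9.3, K12H4.5, rpl-20 and Y17G9B.5, or had as nearest 5′ end that of Y41G9A.17, cmd-1 (calmodulin), F20B6.9, F55C5.17 or ZK899.6, with signals from 60.2 to 84.2. The summit listed by F55C5.17 lay within frm-7, in the snoRNA gene C51F7.4.

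The same strong regions appeared in both replicates more often than chance placement gave. Among the 280 strongest peaks of replicate 1, 109 overlapped one of the 280 strongest of replicate 2 by at least 1 bp (38.9%, 95% Wilson interval 33.4 to 44.8). Rotating the replicate 2 peaks along each chromosome gave a mean of 7.30% and a maximum of 8.93% (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). With nuclear peaks alone, a setting chosen after the data were seen, 86 of 254 overlapped (33.9%) against a rotated mean of 0.226% (one-sided permutation p = 0.001). All 254 nuclear thresholded peaks overlapped some peak of replicate 1, and 250 some peak of replicate 2. That was favoured beforehand, since the thresholded list was taken from the pooled and replicate lists. Of these 254 peaks, 179 overlapped one of the 280 strongest of replicate 1, 130 one of the 280 strongest of replicate 2, and 88 both. The order of the thresholded peaks by signal was shared only in small part. Across 274 thresholded peaks found in both replicates, the log2 signals gave r = 0.69 and rho = 0.31 (permutation p = 1e-05 for each, the smallest possible). The mitochondrial peaks form a cluster of their own, and across the 250 nuclear peaks r was 0.24 (permutation p = 0.0001, adjusted p = 0.0002) and rho 0.093 (permutation p = 0.1, adjusted p = 0.1). These are correlations across peaks within a pair of samples, and peaks are not independent replicates. The peaks were also selected on the pooled signal, which lowers a correlation between its parts.

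**Figure D1:**
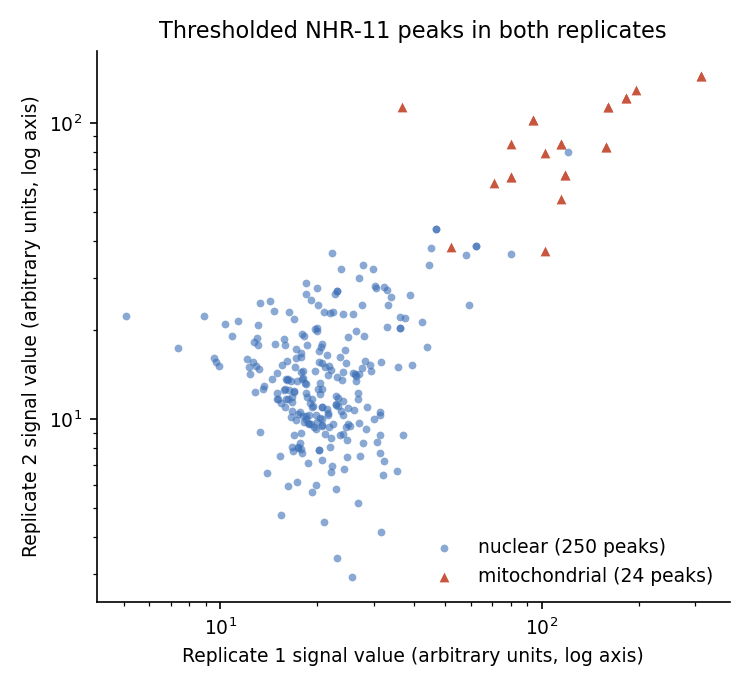
Signal value of each thresholded peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), for the 274 peaks found in both; each point is 1 peak, blue for 250 nuclear and red triangles for 24 mitochondrial peaks, and peaks matched to the same replicate peaks lie on top of one another. The mitochondrial peaks sit at the upper right, and the nuclear peaks form a cloud in which r was 0.24.

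Nuclear peaks lay mostly between genes and in front of them, and rarely in coding sequence. Of the 254 nuclear summits, 141 were intergenic (55.5% against 37.9% after rotation), 51 in introns (20.1% against 32.9%) and 7 in coding exons (2.76% against 24.3%; two-sided permutation, adjusted p = 0.003 for each of these 3 classes). Summits in 3′ UTRs numbered 17 (6.69% against 3.38%, permutation adjusted p = 0.014), and those in 5′ UTRs 8 (3.15% against 1.43%, permutation adjusted p = 0.072). The window from 1000 bp upstream to 500 bp downstream of a protein-coding 5′ end held 148 of all 280 summits (52.9%, Wilson interval 47.01 to 58.6). Rotation placed 36.3% there, with an SD of 2.67 over the rotations (two-sided permutation p = 0.002, the smallest possible). For the nuclear peaks alone the share was 49.6% against 31.2% (permutation p = 0.002).

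Genes for tRNAs, snoRNAs and snRNAs stood close to a large part of the peaks. A summit within 500 bp of a short non-coding gene was found for 92 of the 280 peaks (32.9%, Wilson interval 27.6 to 38.6) against 8.27% after rotation (two-sided permutation p = 0.002). Among the nuclear peaks it was 74 of 254 (29.1% against 1.41%, permutation p = 0.002). By class, 38 nuclear peaks were near a tRNA gene (14.96% against 0.669%), 24 near a snoRNA gene (9.45% against 0.343%) and 10 near an snRNA gene (3.94% against 0.111%), each with a permutation adjusted p of 0.003. Only 2 were near a miRNA gene (0.787% against 0.287%, permutation adjusted p = 0.402). None was near any of 20 annotated nuclear rRNA genes, where rotation placed 0.0189%, so this absence could not be told from chance. The summit itself fell inside a short non-coding gene for 30 nuclear peaks (11.8% against 0.133%, permutation adjusted p = 0.003). Examples chosen after their values were seen are the snoRNA gene C51F7.4 (signal 61.4) and the tRNA gene M02F4.t1 on X (57.9). Short RNA genes often give peaks with many factors. Without an untagged sample or another factor, whether these peaks are particular to NHR-11 cannot be told.

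The X chromosome carried more peaks and chromosome V fewer than their genes would give. X held 72 of the 280 peaks (25.7%, Wilson interval 20.9 to 31.1), while it holds 13.7% of protein-coding genes (two-sided exact binomial p = 7.54e-08). Against its share of chromosome length, 17.7%, the exact binomial p was 0.00072, and against its share of the unthresholded pooled peaks, 19.8%, it was 0.0163. Among the nuclear peaks alone X held 28.3%, and chromosome V 15.4% for 25.004% of the genes (exact binomial adjusted p = 6.96e-09 and 0.000813, over 6 chromosomes). The other 4 nuclear chromosomes did not pass this test, with exact binomial adjusted p of 0.3 for IV and 0.592 for I, II and III. The lower share of V did not pass against its 20.9% of nuclear chromosome length (exact binomial adjusted p = 0.0914) or its 17.8% of the unthresholded nuclear peaks (exact binomial adjusted p = 0.391), comparisons added after the data were seen, while X passed both (exact binomial adjusted p = 0.000199 and 0.00719).

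**Figure D2:**
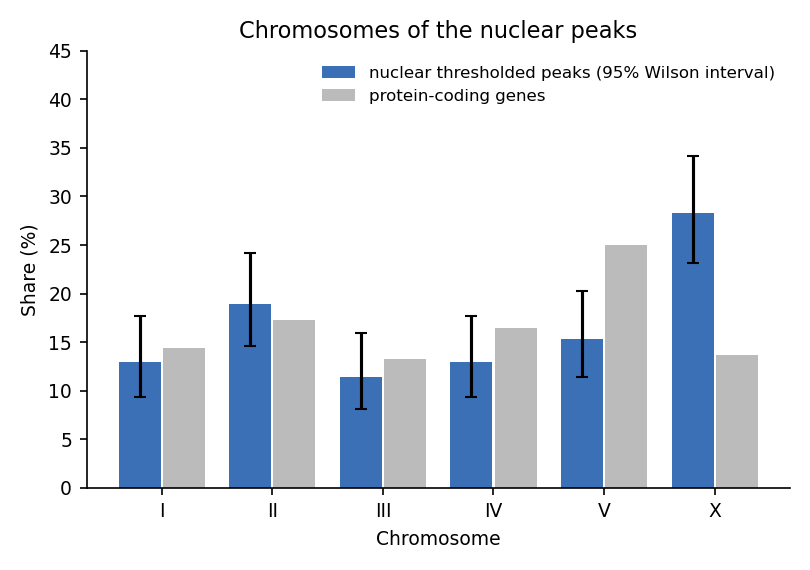
Share of the 254 nuclear thresholded peaks (blue, with 95% Wilson interval) and of nuclear protein-coding genes (grey) on each chromosome, in percent. X held 28.3% of peaks and 13.7% of genes, and V 15.4% of peaks and 25.004% of genes.

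Genes of ribosomal proteins were over-represented near the peaks, and genes of chemosensory receptors under-represented. The peaks in promoter windows belonged to 160 of 19973 nuclear protein-coding genes; 87 nuclear peaks had 1 such gene and 39 had several. Of 83 ribosomal protein genes, 9 were bound where 0.665 would be by chance (odds ratio 15.9, 95% interval 6.86 to 32.6; Fisher's exact test, adjusted p = 7.51e-07 over 35 lists). The 4 with the highest signal were rpl-3, described above, rpl-20 (chromosome IV, 4749873 to 4750302, signal 60.3, summit 310 bp upstream), rpl-35 (III, 7854458 to 7854887, signal 57.5, 461 bp upstream) and rpl-15 (IV, 654737 to 655166, signal 47.1, 376 bp upstream). All 4 summits were intergenic. When each peak was given only to its nearest 5′ end, 4 ribosomal protein genes were left (odds ratio 8.41, Fisher's exact adjusted p = 0.0303), and when the background held only genes with an unthresholded peak the odds ratio was 5.29 (Fisher's exact adjusted p = 0.00526). Chemosensory receptor genes, which act in sensory neurons, had 1 bound member of 1365 (sre-1) where 10.9 would be by chance (odds ratio 0.0851, Fisher's exact adjusted p = 0.0041). Against genes with an unthresholded peak the odds ratio was 0.189 and did not pass (Fisher's exact adjusted p = 0.518). Among the 140 peaks with the highest signal none was bound where 5.47 would be by chance, which did not pass with fewer bound genes (Fisher's exact adjusted p = 0.0737). As for the short non-coding genes, no untagged sample or other factor was at hand. Whether either list result is particular to NHR-11 therefore cannot be told.

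Regulators of larval timing came closest among the other lists, without passing the test. Of 14 heterochronic genes, which set the order of larval stages, mab-10 and lin-42 were bound (odds ratio 20.9, Fisher's exact adjusted p = 0.0636). The mab-10 peak (signal 37.2, summit 308 bp upstream) ranked 816 in replicate 1 and 72 in replicate 2. That of lin-42 (signal 35.1, summit in a coding exon 365 bp downstream of an annotated 5′ end) ranked 101 and 1195. The adjusted p of the heterochronic list was 0.038 with nearest 5′ ends alone, 0.0245 among the 140 strongest peaks and 0.0399 without peaks near short non-coding genes, but 0.126 with windows from 2000 bp upstream, 0.518 against genes with an unthresholded peak, and 0.523 and 0.595 without replicate 1 and 2 (Fisher's exact test in each). Vacuolar ATPase genes had 2 of 21 bound (vha-13, signal 34.3, and vha-12, signal 29.0; Fisher's exact adjusted p = 0.106). The vha-12 peak ranked 456 in replicate 1 and 2388 in replicate 2, and that of vha-13 ranked 259 and 188. In the respiratory chain list cox-5B (signal 57.7) and cox-6A (35.2) were bound among 43, and in the translation factor list iff-2 (29.7) and eif-3.J (29.5) among 39, both with a Fisher's exact adjusted p of 0.271. Ranks in replicates 1 and 2 were 57 and 35 for cox-5B, and 93 and 889 for cox-6A. For iff-2 they were 936 and 147, and for eif-3.J 160 and 2681. Leaving out replicate 2, which uses the 280 strongest unthresholded peaks of replicate 1 alone, raised vacuolar ATPases to 3 of 21 (Fisher's exact adjusted p = 0.00679). Leaving out replicate 1 in the same way raised translation factors to 3 of 39 (Fisher's exact adjusted p = 0.0413).

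The tissue and metabolic lists held few bound genes. Of the hypodermis and seam markers, wrt-3 and the junction gene ajm-1 were bound among 47 (signals 28.7 and 28.5; Fisher's exact adjusted p = 0.273), both by peaks within 500 bp of a short non-coding gene. The same was true of pqn-71, col-85, clec-126 and cox-6A, and of rps-12 among the 9 ribosomal protein genes. Without such peaks, a setting chosen after the data were seen, 8 ribosomal protein genes were bound (odds ratio 17.9, Fisher's exact adjusted p = 1.86e-06). The germ line list had puf-9 (57.7), the pharynx list pqn-71 (39.3), and the intestine, body wall muscle and neuron lists none of 32, 37 and 36. Single members were bound in the lists of nuclear hormone receptors (nhr-68, signal 27.6, of 274), homeobox genes (ceh-38), forkhead factors (fkh-7), glutathione S-transferases (gst-5), collagens (col-85), molting genes (lin-42), heat shock proteins (hsp-1, signal 43.1), histones (his-37), neuropeptides and insulins (ins-39), C-type lectins (clec-126) and Wnt signalling (mig-5). Some of the peaks in these lists ranked far apart in replicates 1 and 2, such as wrt-3 (305 and 4828), ceh-38 (100 and 3421) and gst-5 (132 and 3679). Others ranked close, such as nhr-68 (410 and 408), fkh-7 (442 and 459), col-85 (332 and 318) and ajm-1 (352 and 377). None was bound among 111 lipid metabolism genes, 75 cytochrome P450 genes, 67 UDP-glucuronosyltransferase genes, 30 short-chain dehydrogenase genes or 6 vitellogenin genes. The same held for GATA factors (12), basic helix-loop-helix and bZIP factors (61), proteasome genes (31), lysozymes, saposins and antimicrobial peptides (93), ABC transporters (55), major sperm proteins (31) and insulin and TOR signalling (19). With 160 bound genes most of these lists had an expected count under 1, so an absence in them could not be told from chance.

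**Figure D3:**
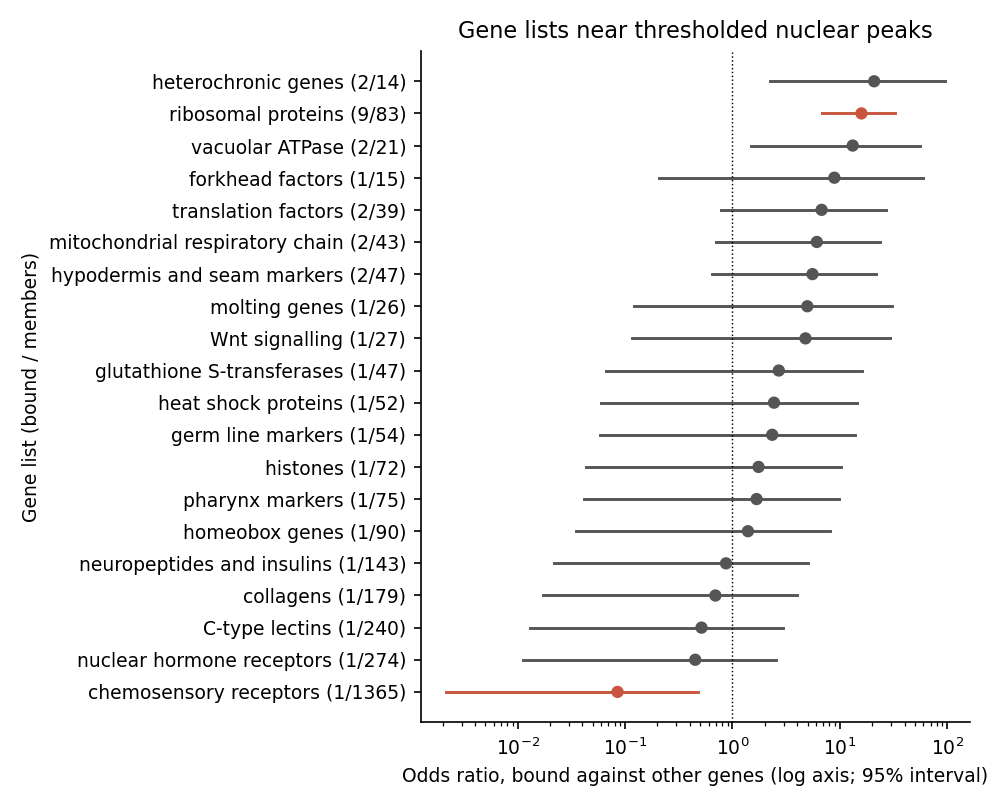
Odds ratio (log axis) with 95% interval for each gene list with at least 1 bound member, comparing genes with a thresholded summit in their promoter window with all other protein-coding genes; bound and total members are in brackets, and red marks an adjusted p under 0.05. Ribosomal proteins had an odds ratio of 15.9 and chemosensory receptors one of 0.0851.

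Summit sequences were richer in G and C than their flanks, and no excess of the hexamers that nuclear receptors bind was found in them. The 101 bp at nuclear summits had 44.8% G and C against 36.9% in the flanks, a difference of 7.97 points (SE 0.715 over 254 peaks, permutation p = 0.0001). AGGTCA, the core hexamer of many nuclear receptor sites, was in 5 of 279 summit windows (1.79%) and in 2.87% of flanks, AAGTCA in 2.87% and 3.76%, and AGTTCA in 3.58% and 6.27%. None of these 3 passed an exact test that treats each peak's summit and flank windows as exchangeable (adjusted p = 0.752, 0.803 and 0.348). The direct repeat of RGKTCA (R for A or G, K for G or T) with 1 spacer base was in no window. That pattern takes in AGGTCA and AGTTCA but not AAGTCA, and other spacings were not searched. The direction for AGGTCA turned without replicate 2 (2.87% against 2.33%). It also turned with windows of 100 bp on each side and flanks 500 bp away (5.73% against 5.56%). In that exact test, 4 of 20 motifs were enriched and 1 was depleted, while 7 had an unadjusted p under 0.05. The enriched ones were GAGACGCAG (4.66% against 0.538%, exact adjusted p = 0.00232), the GC box GGGCGG (6.09% against 1.97%, exact adjusted p = 0.0214), the B box of tRNA gene promoters (8.24% against 3.23%, exact adjusted p = 0.0214) and the scrambled hexamer ACTGAG included as a negative control (5.38% against 1.79%, exact adjusted p = 0.0308). A run of 8 T bases was depleted (3.94% against 9.32%, exact adjusted p = 0.0214). Of 2080 hexamers counted with their complements, 73 were enriched and 32 depleted, led by ACGCAG (12.9% against 1.79%, exact adjusted p = 1.99e-07) and CTGCGC (8.96% against 0.358%, exact adjusted p = 1.99e-07). Without replicate 1, 26 hexamers were enriched, 17 of them among the 73, and 8 were depleted. Without replicate 2, 65 were enriched, 36 of them among the 73, and 23 were depleted. Windows of 100 bp on each side and flanks 500 bp away together gave 171 enriched hexamers, 56 of them among the 73, and either change alone gave a count between 73 and 171. Of the 4 enriched motifs only GAGACGCAG and the B box passed without replicate 1, where the GC box and the scrambled hexamer each had an exact adjusted p of 0.148, and the T run did not pass without replicate 2 (exact adjusted p = 0.106). The scrambled control passed more clearly without replicate 2 (exact adjusted p = 0.00283, the same as for GAGACGCAG and the B box) and with the wider windows and farther flanks (exact adjusted p = 1.9e-05). Among the 140 strongest peaks 13 hexamers were enriched and 6 depleted, and no motif of the 20 passed, with 4 at an unadjusted p under 0.05 in the exact exchange test.

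This exchange test was chosen after the data were seen. The sign test chosen beforehand sets 1 summit window against 2 flanks and is tilted towards the flanks: it called 44 motifs depleted in 40 simulated sets with no difference, and the exchange test none. Those sets were placed at random and lack the higher G and C content of the real summits, so they do not cover a difference in base composition. The enriched motifs and hexamers were not separated from that difference, and the scrambled control was among them. The B box belongs to tRNA gene promoters, and motifs were not tested without peaks near tRNA genes. Its excess is therefore not separate from the closeness of 38 nuclear peaks to tRNA genes. On the real peaks the sign test called 0 motifs and 15 hexamers enriched. Of 9 motifs at an unadjusted p under 0.05 in it, GAGACGCAG alone was more frequent at summits, and its depletion calls are left out. With unthresholded summits as control, a comparison chosen beforehand, the B box (8.21% against 2.21%, Fisher's exact adjusted p = 8.46e-05) and the GC box (6.07% against 2.36%, Fisher's exact adjusted p = 0.0196) were enriched and the T run was depleted (3.93% against 11.4%, Fisher's exact adjusted p = 0.000512). GAGACGCAG and the scrambled hexamer did not pass there (Fisher's exact adjusted p = 0.11 and 0.313).

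The nhr-11 gene itself had no peak. None of the thresholded, pooled or replicate lists had a peak within 2000 bp of nhr-11 (chromosome IV, 9070003 to 9073622). In both replicates the gene lay in a stretch without any called peak from 9041747 to 9087893, 46147 bp long, which was the fifth longest of 37725 such stretches on the nuclear chromosomes, whose median length was 1323 bp. The 5 other protein-coding genes wholly inside it were Y73F4A.2, Y73F4A.1, mppb-1, mans-4 and twk-8. On either side, over an equal length, replicate 1 had 12 and 17 peaks and replicate 2 had 10 and 17. The unc-119 locus (chromosome III, 10902641 to 10908935) had no thresholded peak within 2000 bp, and 1 weak pooled peak of signal 9.32.

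**Figure D4:**
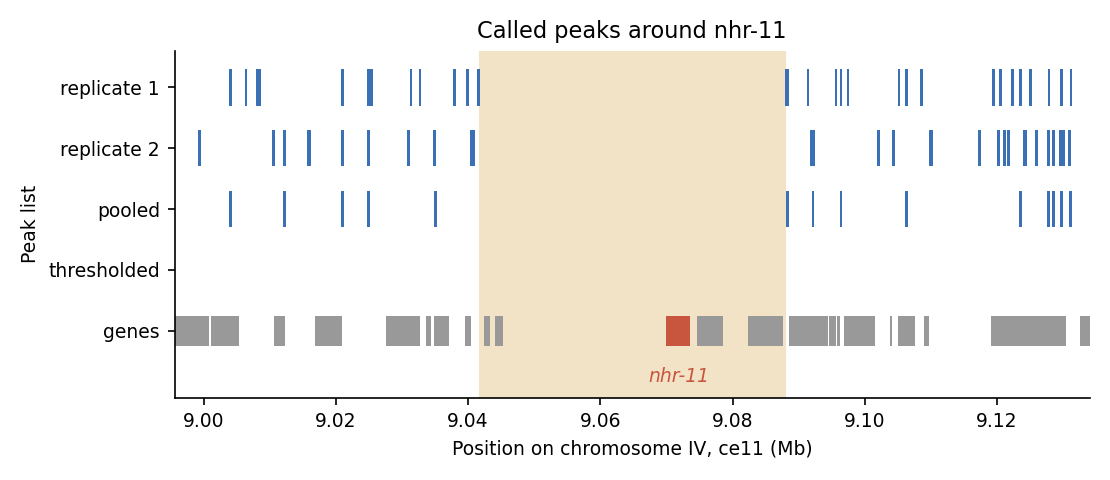
Called peaks (blue bars) of each list along chromosome IV in Mb (ce11), with protein-coding genes in grey and nhr-11 in red; the shaded span is the 46147 bp without a peak in either replicate. Replicate 1 has 12 peaks to the left and 17 to the right of the span, and no thresholded peak falls in the region drawn.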

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

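The window exchange test, the changes of window or flank distance alone, and all settings without mitochondrial peaks or without peaks near short non-coding genes were chosen after the data were seen. Peak number, replicate overlap, signal correlation by r, promoter share, short non-coding gene share, X share and the nhr-11 locus kept their direction and side of the threshold in every alternative run, with overlap from 29.6% to 43.6%, promoter share from 40.7% to 64.6%, X share from 21.8% to 28.6% and r from 0.24 to 0.89. The rank correlation did not: rho was 0.31 and fell to 0.093 without mitochondrial peaks (permutation adjusted p = 0.1). Enriched gene lists rose from 1 to 2 with nearest 5′ ends alone, 2 among the 140 strongest peaks, 2 without peaks near short non-coding genes, and 2 without either replicate. Depleted lists fell from 1 to 0 against genes with an unthresholded peak and to 0 among the 140 strongest peaks. By the sign test 0 motifs were enriched, against 4 with windows of 100 bp on each side and flanks 500 bp away together, 1 with those windows alone, 2 with those flanks alone, 2 with unthresholded summits as control, and 0 to 1 without a replicate. By the exchange test 4 were enriched, 4 without mitochondrial peaks, 0 among the 140 strongest peaks, 2 to 5 without a replicate, 5 with the wider windows and farther flanks together, 5 with the windows alone and 3 with the flanks alone. Hexamers went from 15 to 3 among the 140 strongest peaks, which are fewer peaks to test, 36 with both the wider windows and the farther flanks, 25 with the windows alone, 27 with the flanks alone, and 2 to 13 without replicate 1 or 2. By the exchange test they numbered 73, 72 without mitochondrial peaks, 13 among the 140 strongest peaks, 26 to 65 without replicate 1 or 2, 171 with both the wider windows and the farther flanks, and between 73 and 171 with either alone. The exchange test differs from the sign test in its weighting of the flanks; for the other changes the cause was not tested. The nhr-11 locus was not run on ce10, since ce10 gene coordinates were not used here; the ce10 lists had a stretch without peaks in either replicate on chromosome IV from 9041748 to 9087874, 46127 bp long and ranked 6 by length. No paired analysis was possible because there is 1 group. Depth is unknown and limits which weaker sites could be called.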

Other observations

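The tests of mitochondrial coverage, of the transgene and of X against unthresholded peaks with and without those near short non-coding genes, and the counts of X peaks by class, were chosen after the results were seen. Peaks on X differed in position from those on the autosomes. Of the 72 X peaks 24 lay in promoter windows (33.3%), against 102 of 182 autosomal peaks (56.0%; Fisher's exact p = 0.00132). Outside promoter windows X held 48 of 128 nuclear peaks (37.5%, exact binomial p = 1.21e-06 against its 18.97% of the bases outside such windows), and in promoter windows 24 peaks, or 19.05% (exact binomial p = 0.209 against 14.9% of the bases). Near short non-coding genes X held 28 of 74 peaks (37.8%), and X carries 45.1% of the nuclear tRNA genes. Many bound promoters were shared by neighbouring genes. Examples, chosen after their values were seen, are top-2 with npp-3 (signal 52.2), and fib-1, the fibrillarin gene, with mut-15 (30.1).

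The mitochondrial peaks covered 54.7% of the 13794 bp mitochondrial genome, while nuclear peaks covered 0.107% of the nuclear genome. Reads shared with nuclear copies are argued against, since 3.85% of the mitochondrial peaks, 1 of 26, matched nuclear sequence over at least 100 bp at 90% identity. Whether abundant mitochondrial DNA was called along its length stays open, since the coverage of 54.7% was known before a bound was set for it. Mitochondrial content in the ChIP and control libraries was not measured, as the control was not analysed here, and no biological explanation was tested.

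The stretch without peaks around nhr-11 was rare: 0.441% of protein-coding genes lay in one at least as long in both replicates, which argues against an ordinary gap, although with the pooled list alone the share was 4.59%. Reads that cannot be placed uniquely stay open as part of the cause, since 76.3% of the 32-base words in the stretch occur once in the genome. That share was 90.8% and 99.2% in its flanks and 4.30% to 60.02% in the other 9 of the 10 longest stretches. As the whole cause such reads are argued against. Most words in the stretch can be placed, yet it held 0 peaks where each flank held 10 to 17 per replicate. A second hypothesis is that the transgene carries extra copies of this region, which could raise the control there if that library came from the same strain. The length of 46147 bp would suit a fosmid insert, but copy number needs read depth, so its part cannot be told apart from that of unplaceable reads. No biological explanation was tested.

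The excess of peaks on X over its share of genes was not accounted for by clusters of short non-coding genes alone, since X still held 24.4% of the 180 nuclear peaks away from such genes (Wilson interval 18.7 to 31.2). Nor was it fully present before thresholding, as the thresholded nuclear share of 28.3% exceeded the 19.9% of unthresholded nuclear peaks (exact binomial p = 0.0012), although that share was itself above the 13.7% of genes. The 2 together are not excluded: away from short non-coding genes, the 24.4% did not pass against the 19.2% of unthresholded peaks (exact binomial p = 0.0878). It also stays open that X in larvae of mixed sex may differ in chromatin from the autosomes, which these lists cannot test. No biological explanation was tested.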
